A study of Mus musculus with 20 samples.

How the data were processed

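The series holds 20 RNA-seq libraries from mice 100 days old that carry the ApcMin allele, which predisposes to intestinal tumors. Per the labels, RNA was taken with a Maxwell kit from colorectal tumors and from adjacent epithelium outside the tumors, and libraries were made with a stranded mRNA kit (TruSeq Stranded mRNA). In 1 genotype a floxed Erbb2 gene was combined with a cre transgene under the Vil1 promoter, which is active in intestinal epithelium. These animals are called Erbb2-deficient here. Littermates with the floxed gene and without cre served as controls. The 4 groups of genotype and tissue hold 5 libraries each, and groups and replicate numbers were taken from the labels. The genotypes also differ by the presence of the cre transgene. The labels do not state that equal replicate numbers mark the same mouse, so p-values measure the spread between libraries.

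Each deposited file holds unnormalized read counts per gene symbol, 1 file per library. Per the submitters' processing notes, Trimmomatic, HISAT2 version 2.2.1, HTSeq version 2.0.2, DESeq2 and genome build mm39 were used. The role and settings of each tool, including the strand setting of the counting step, are not given in the sources used here. Every file has 46329 gene rows in the same order, of which 18657 are at 0 in every library, and 5 summary rows that name no gene. The summary rows were left out of library sizes and tests. Reads that fell on no counted feature made up 78.6% to 85.1% of the reads in a file. Reads with more than one alignment made up 6.13% to 11.5%, reads of low alignment quality 3.86% to 5.65%, unaligned reads 1.52% to 2.48%, and ambiguous reads 0.0309% to 0.0868%. Reads on genes made up 2.51% to 3.45%, or 1071737 to 1944309 counts per library, with a median of 1258396. The median row tested without a listed gene on the opposite strand had a mean of 15.7 counts, so its counting error is large.

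Because so few reads lay on genes, the strand of the counted reads was examined with GENCODE M21 (assembly GRCm38). That annotation is of another build than the counts, so it was used only for names and for which genes overlap or neighbour each other, and no coordinate is given. Of the counted symbols, 34632 matched. A row was classed by whether an annotated exon of another gene overlaps its exons on the opposite strand (6686 rows), whether the span of an opposite-strand gene, widened by 1000 bases, meets its exons without such an overlap (6726 rows), or neither (21220 rows). The other 11697 rows were not matched. The gene on the opposite strand is called the partner of a row.

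Gene differences were tested with edgeR version 4.0.16 in R version 4.3.3. Rows were filtered with filterByExpr by group at its minimum count of 10, which kept 7119 rows, and libraries were scaled with TMM factors. A means model of the 4 groups was fitted to all 20 libraries with robust dispersion estimates, and quasi-likelihood F tests gave p-values with Benjamini-Hochberg adjustment at 0.05. The comparisons were genotype within tumors, genotype within adjacent tissue, tumor against adjacent tissue within each genotype, and the interaction of genotype and tissue. The standard error of a log2 fold change was its size divided by the square root of F. Normalized CPM is the CPM over tested rows after TMM scaling, and log2 CPM adds a prior count of 2.

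The 43 gene lists, the tests, the comparisons, the rule for named genes and most alternatives were fixed before the data were examined. Lists were tested with camera (limma version 3.58.1) at a preset correlation of 0.01, where at least 3 members passed the filter, which held for 28 lists. The mitochondrial members of 1 list were matched to the symbols that the files use after these had been seen. The rule named Erbb2 and the other members of the ERBB list. Per comparison it named the 10 largest rises and the 10 largest falls by fitted log2 fold change among genes past the threshold, with a mean of at least 5 CPM and no overlap between the groups compared, the last condition not applying to the interaction. Symbols of predicted genes (Gm with a number, or ending in Rik) and of antigen receptor segments were skipped. Where fewer than 5 passed in a direction, the genes of smallest p were taken up to 5. For a described list up to 4 members of smallest p were named. For tumor against adjacent tissue, genes were picked in the control mice, with values in Erbb2-deficient mice beside them.

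Both steps were tested on simulated counts with 200 changed genes, drawn from the means and dispersions of the real libraries. In the simulated tumor genotype comparison (6828 genes) 13% of genes changed 2-fold and 59% of genes changed 4-fold were called, with 2 false calls. In the simulated adjacent genotype comparison (6791 genes) 13% of genes changed 2-fold and 69% of genes changed 4-fold were called, with 2 false calls. In the simulated interaction (6823 genes) 1 of 100 genes changed 2-fold and 29 of 100 changed 4-fold were called, with 0 false calls. In the simulated control tumor against adjacent comparison (6781 genes) 17% of genes changed 2-fold and 65% of genes changed 4-fold were called, with 6 false calls among 88, and in the Erbb2-deficient one (6831 genes) 12% and 68%, with 2. The planted list was called in each simulation, and none of the unchanged lists. Genes were drawn independently of each other, so the simulation cannot show how often correlated list members give false list calls.

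Alternatives were RLE and upper-quartile scaling, no filter and a filter of 1 CPM in 5 libraries, DESeq2 version 1.42.0, non-robust moderation, a replicate block, a sex term, smooth muscle and B cell covariates, fits on the compared groups alone, a fold threshold of 1.5 with glmTreat, and leaving out each library. Lists were tested again with both scalings, the replicate block, libraries left out, an estimated correlation and fry. No list results are given for other filters, DESeq2, non-robust moderation, the sex term, the covariates, fits on the compared groups alone or glmTreat. Alternatives chosen after seeing the data left out control tumors 2 and 3, left control tumor 2 out where it enters only the shared estimate of the spread, kept only rows without a known opposite-strand exon, and replaced list members by the rows whose exons overlap them. Rows and list members without an opposite-strand exon include unmatched ones, whose strand class is not known. Of the 3935 such rows tested, 1210 were unmatched. No 2 libraries of a group agreed within sampling noise. The lowest chi-square per degree of freedom between 2 of them was 4.19, over rows with at least 10 counts in the pair. The check for single libraries far from their group was first run on log2 CPM of the named rows. It was then changed to normalized CPM, leaving out groups with no library over 3 counts, after the first result had been seen, because prior counts made groups at 0 look spread out.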

Results

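The study asked how loss of Erbb2, a receptor tyrosine kinase of the EGF receptor family, in the intestinal epithelium of ApcMin mice relates to gene expression in colorectal tumors and in the tissue next to them. RNA was sequenced from 5 tumors and 5 adjacent samples of Erbb2-deficient mice and from as many of littermate controls.

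Most counts were on rows that lie opposite another gene. The row of ND6, the only mitochondrial protein gene on its strand, held 22599 to 199495 counts per library, more than the rows of the other 12 mitochondrial protein genes together (884 to 5698) in all 20 libraries. Rows with an exon of another gene on the opposite strand made up 19.3% of the matched rows and held 77.2% of their counts. Of 168 matched rows with a mean of at least 1000 counts, 144 had such an exon. Rows of abundant housekeeping genes had few counts, with a mean of 3.85 for Gapdh and 145 for Eef1a1, the highest of 10 looked at. The Tsix row, which overlaps the female-specific transcript Xist, held up to 2038 counts in a library, and the Xist row at most 51. Stranded reads counted on the opposite strand would give these values. A row with an exon opposite can then hold mostly reads of its partner. In what follows a symbol names a row of the files and a list is a set of rows, not measured transcripts of those genes. Within a row, the reads of its gene and of its partner cannot be told apart. Partners or neighbours on the opposite strand are given for some rows, and a row named without one can also have one in GENCODE M21.

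**Figure D1:**
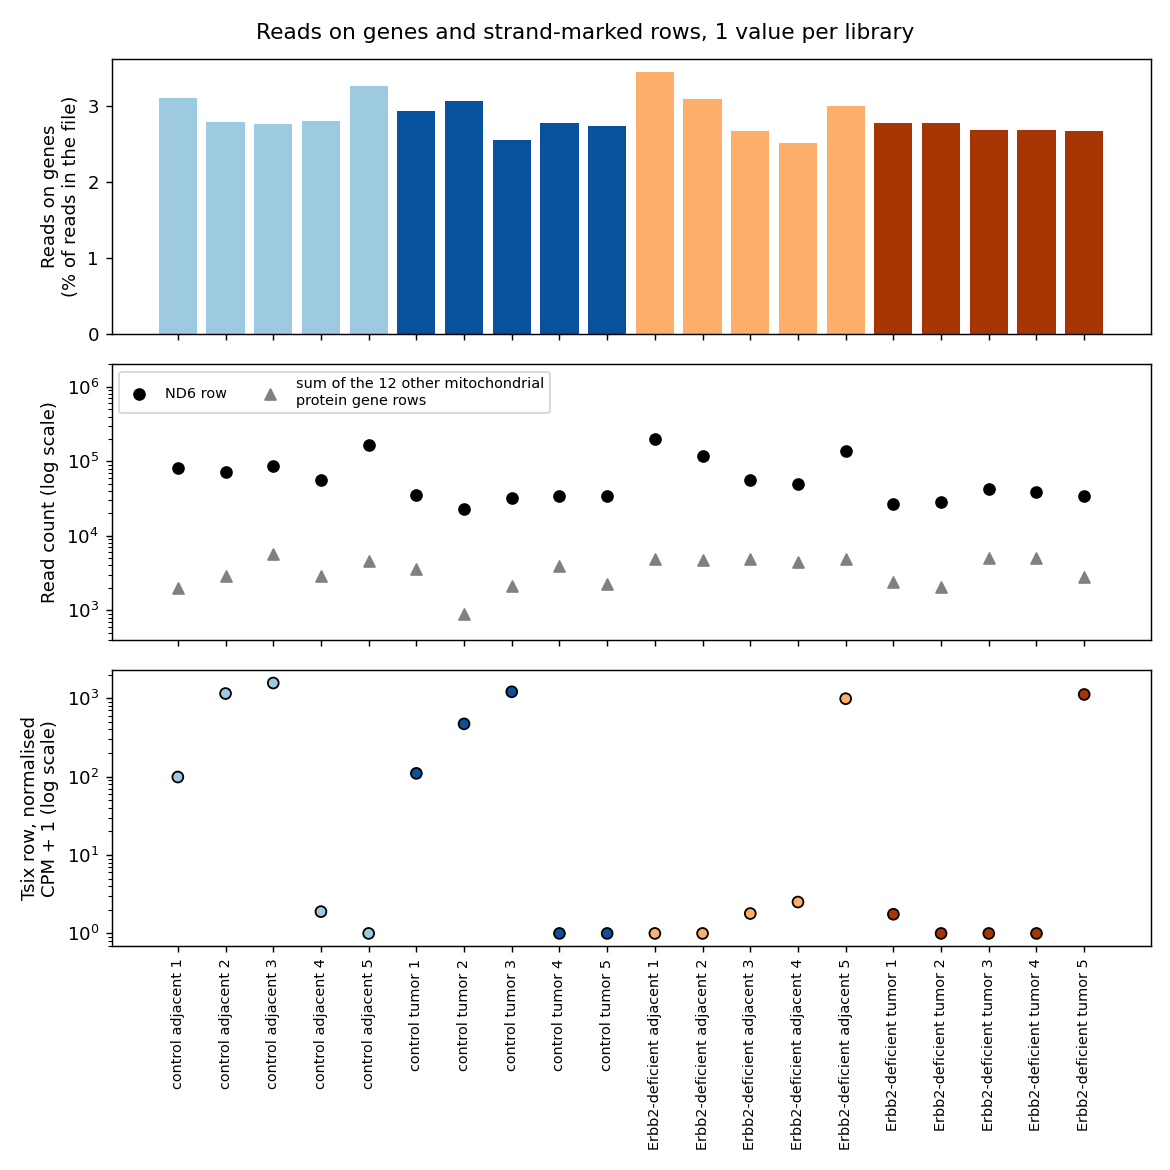
Share of reads on genes (percent), counts of the ND6 row and of the 12 other mitochondrial protein gene rows (log scale) and normalized CPM of the Tsix row (log scale), 1 value per library. ND6 exceeded the other rows together in all 20 libraries, and Tsix was above 50 CPM in 8 libraries.

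Control tumors 2 and 3 stood apart from the other tumors. In the principal components of log2 CPM, the first component (42.4% of variance) ran from tumors to adjacent tissue and the second (21.3%) set control tumor 2 apart from the other 19 libraries. Control tumor 2 had 0 counts in the rows of the epithelial genes Epcam, Krt8 and Muc2, and 501 CPM in the Bcl9l row (opposite the B cell chemokine receptor Cxcr5), 482 CPM in the Dexi row (opposite the MHC class II regulator Ciita) and 141 CPM in the row of Cd74, the MHC class II invariant chain. These 6 rows were chosen after their values were seen. Its median Spearman correlation with the other control tumors was 0.636, against 0.820 to 0.926 for the other 19 libraries within their groups. Control tumor 3 lay at -3.75 on the first component, between the adjacent libraries and the other tumors. It had 483 CPM in the row of the goblet cell mucin Muc2. In that row control tumors 1, 4 and 5 had 15.2 to 22.8 CPM and Erbb2-deficient tumors 10.5 to 241 CPM. The Tsix row was above 50 CPM in both libraries numbered 1, 2 and 3 of the controls and in both numbered 5 of the Erbb2-deficient mice, so that sex by this row was uneven between the genotypes. All 20 libraries were kept in the tests.

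**Figure D2:**
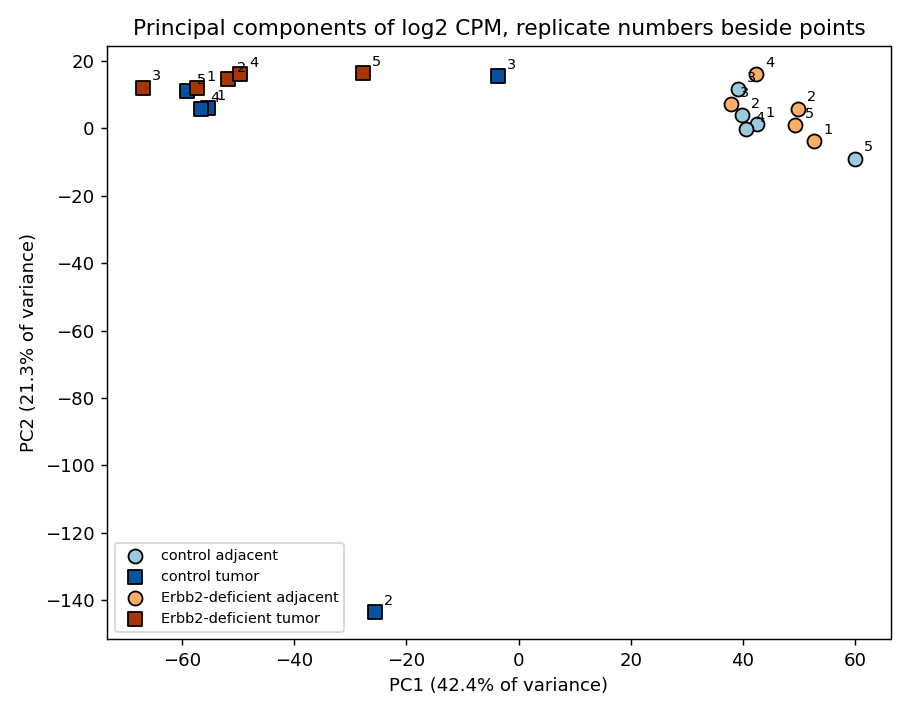
First 2 principal components of log2 CPM over 7119 rows, axes in component units with the percent of variance, 1 point per library. Control tumor 2 lay at -144 on the second component, and control tumor 3 at -3.75 on the first.

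The targeted gene could not check the labels. The Erbb2 row held 1 to 22 counts per library. If reads were counted on the opposite strand, this row would miss most Erbb2 reads. Those from exons that overlap Mien1 would then fall on the Mien1 row. Any Erbb2 reads would also include those from cells without cre and from exons outside any deleted part. The level of the Erbb2 row was 10.5 ± 5.19 CPM (SD, n = 5) in Erbb2-deficient and 6.97 ± 3.96 CPM in control adjacent tissue. In tumors it was 4.44 ± 2.87 CPM in Erbb2-deficient and 4.31 ± 2.30 CPM in control mice. Neither genotype difference passed the edgeR test, with a log2 fold change of 0.60 ± 0.52 SE in adjacent tissue (adjusted p = 0.927) and 0.02 ± 0.60 SE in tumors (adjusted p = 0.994). The tumor value had no firm sign, at -0.32 without Erbb2-deficient tumor 4 and 0.28 without Erbb2-deficient tumor 5. The Mien1 row, chosen after its values were seen because it overlaps Erbb2 on the opposite strand, held 4 to 548 counts. The Mien1 row also lies opposite Gm12352. Its log2 fold change between genotypes was -0.41 ± 0.64 SE in adjacent tissue (edgeR adjusted p = 0.985) and -0.41 ± 0.65 SE in tumors (adjusted p = 0.883).

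**Figure D3:**
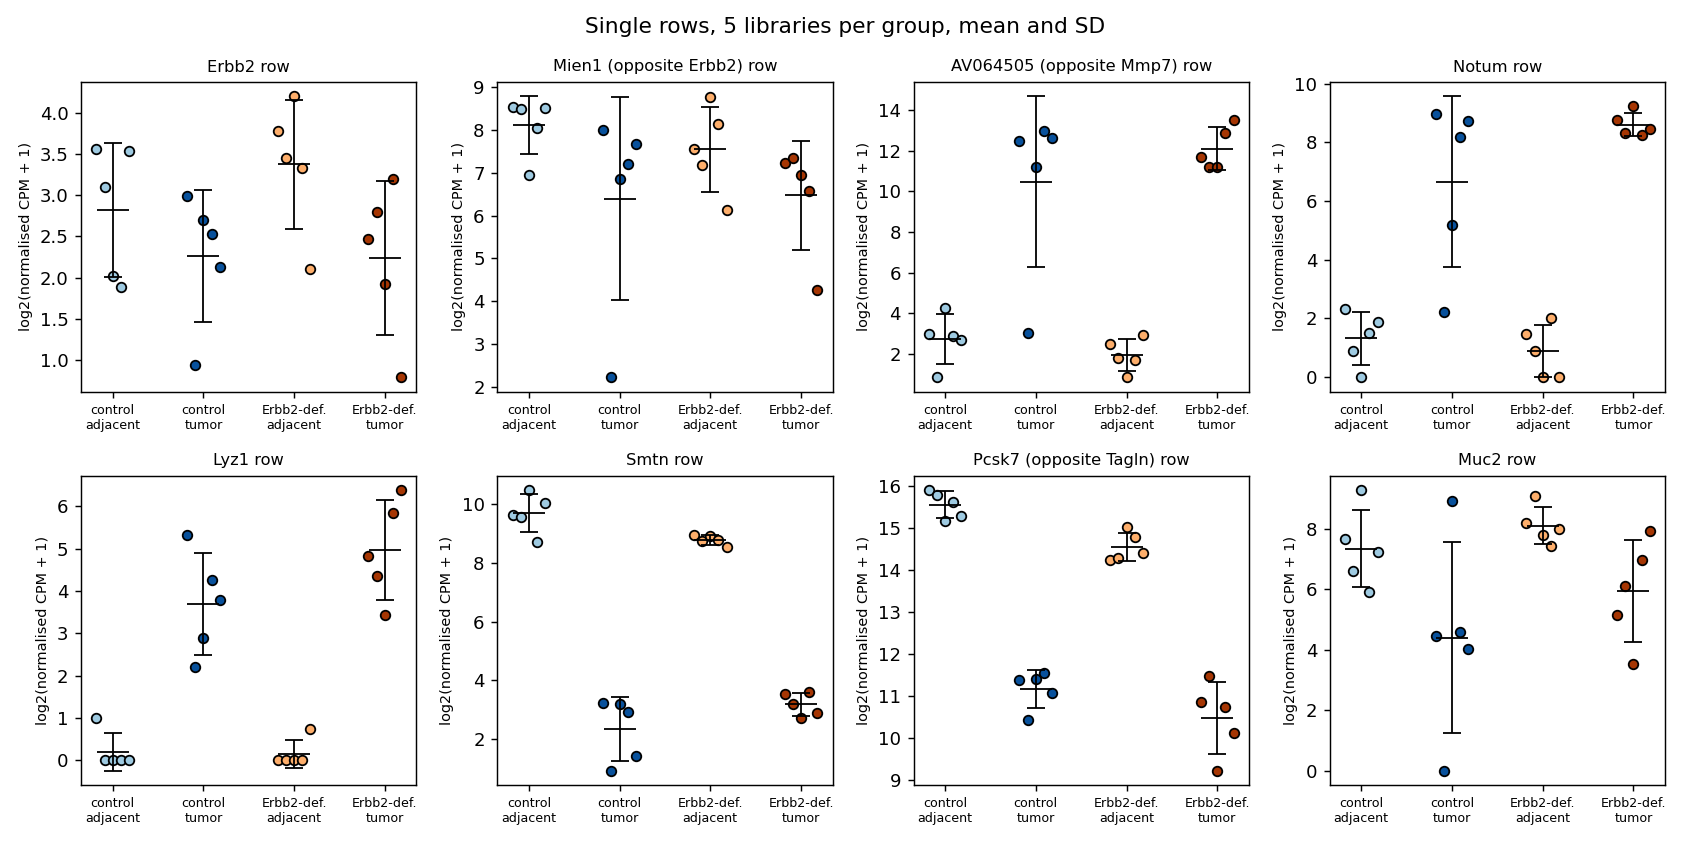
log2 of normalized CPM plus 1 for 8 rows, 1 point per library, with mean and SD of the 5 libraries of each group. The AV064505 row (opposite Mmp7) averaged 3.37 CPM in adjacent tissue and 5501 CPM in tumors of Erbb2-deficient mice, and the Smtn row 884 and 5.18 CPM in those of control mice, while the Erbb2 row lay between 0.720 and 17.5 CPM in every library.

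Of the other members of the ERBB list, Egfr, Nrg4 and Lrig1 passed the count filter, and none passed between genotypes. The Nrg4 row, opposite Fbxo22 and Gm15625, rose in tumors. Its log2 fold change was 0.72 ± 0.16 SE in controls (edgeR adjusted p = 0.00299) and 0.48 ± 0.16 SE in Erbb2-deficient mice (adjusted p = 0.0282). The Nrg4 call was lost in 3 of 23 alternatives in controls (range of adjusted p 2.25e-05 to 0.999), among them the test against a 1.5-fold change, and in 6 of 24 in Erbb2-deficient mice (0.00427 to 0.964). The Egfr row averaged 16.6 CPM in control adjacent tissue and 6.77 CPM in control tumors (4.09 without control tumor 3), and did not pass (edgeR adjusted p = 0.0642), but did in 5 of 24 alternatives (range 0.00373 to 0.998), 1 of them without control tumor 3. Lrig1, opposite Slc25a26, passed in neither genotype. Erbb3, Erbb4, the ligands Egf, Tgfa, Areg, Ereg, Btc, Hbegf, Epgn, Nrg1 and Nrg2, and the inhibitor Errfi1 had means of at most 6.35 counts and were not tested. The housekeeping gene Gapdh had a mean of 3.85 counts, so such counts do not show low expression.

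The comparison of tumors with adjacent tissue in control mice asked which genes mark tumors when Erbb2 is intact. Most tested smooth muscle and absorptive colonocyte rows and 3 of 10 goblet cell rows fell in tumors, and most Wnt target rows rose. Of 14 tested smooth muscle members 12 fell and 0 rose (12 fell adjusted over the list alone). Smtn, a smooth muscle cytoskeletal protein, averaged 884 CPM in adjacent tissue and 5.18 CPM in tumors, a log2 fold change of -7.37 ± 0.46 SE (edgeR adjusted p = 2.29e-09). The smooth muscle myosin Myh11 averaged 140 and 2.64 CPM, calponin Cnn1 48.3 and 1.24 CPM, and tropomyosin Tpm2 92.7 and 3.83 CPM. Camera called this list at adjusted p = 5.71e-23 (adjusted p = 0.00198 with an estimated correlation).

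Wnt targets rose in control tumors in 8 of 10 tested members (9 adjusted over the list alone). The Notum row, of a secreted Wnt inhibitor (opposite Notumos and Myadml2os), averaged 1.85 CPM in adjacent tissue and 250 CPM in tumors, a log2 fold change of 7.07 ± 1.01 SE (edgeR adjusted p = 9.76e-05). Lef1 averaged 2.54 and 26.2 CPM (16.2 without control tumor 2), and Dkk2 0.545 and 11.9 CPM. The Prox1 row (opposite Prox1os) averaged 0.153 CPM in adjacent tissue, from 1 count in control adjacent 3, and 15.9 CPM in tumors. Camera gave this list adjusted p = 8.38e-05 (adjusted p = 0.446 with an estimated correlation). Absorptive colonocyte markers fell in 4 of 6 tested members (5 adjusted over the list alone), namely the carbonic anhydrase Car4 (16.8 and 1.10 CPM, 0.227 without control tumor 3), Cdhr5, the chloride exchanger Slc26a3 and Muc3 (whose call was lost in 7 of 24 alternatives). Goblet cell markers fell in 3 of 10 (4 adjusted over the list alone), namely Clca1 (73.3 and 6.32 CPM, 2.84 without control tumor 3), Fcgbp and Tff3, while Bcas1 (opposite Bcas1os1 and Bcas1os2) did not pass over all genes (edgeR adjusted p = 0.0550). Camera gave adjusted p = 0.00100 for the colonocyte and 0.00551 for the goblet cell list (adjusted p = 0.446 and 0.593 with an estimated correlation). The goblet cell list was not called without control tumor 2, which had 0 counts in Muc2 (camera adjusted p = 0.0748, range over its alternatives 4.71e-05 to 0.593). Mitochondrially encoded rows fell in 4 of 12 (5 adjusted over the list alone): ND6 (81151 and 27336 CPM), ND2, CYTB and ND1. ND6 lies on another strand than the other mitochondrial protein genes. If reads were counted on the opposite strand, its row would hold RNA of another strand than their rows, and the list would mix both. Of 24 alternatives the calls were lost in 18 for ND1, 13 for CYTB and 8 for ND2. Camera gave that list adjusted p = 0.0292 (adjusted p = 0.861 with an estimated correlation). It was not called without control tumor 2 (0.156), 3 (0.0920) or 5 (0.0550), or without control adjacent 3 (0.0812) or 5 (0.0883), with a range over its alternatives of 0.00308 to 0.861.

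Among single rows, the 10 largest rises in control tumors by the rule were LOC115489436, the Paneth cell lysozyme Lyz1, Tcfl5 (opposite Col9a3), T2, Extl1, Arv1 (neighbour Ttc13), Rcan3, Mir1905 (opposite Mex3a), Spatc1 (opposite Mirt2) and Marcksl1 (neighbour Hdac1). All 10 also rose in Erbb2-deficient tumors (edgeR adjusted p at most 0.000584). Extl1 averaged 30.5 CPM in adjacent tissue and 819 CPM in tumors of controls, and 26.9 and 1425 CPM in Erbb2-deficient mice. Arv1 averaged 31.4 and 679 CPM in controls, and 23.0 and 861 CPM in Erbb2-deficient mice. Lyz1 averaged 0.197 and 16.0 CPM in controls (10.2 in tumors without control tumor 1), and 0.132 and 39.2 CPM in Erbb2-deficient mice. Its adjacent mean came from 1 count in each genotype. Marcksl1 had a log2 fold change of 3.75 ± 0.49 SE in controls and 3.88 ± 0.48 SE in Erbb2-deficient mice. The 10 largest falls were Chrm2, Riiad1 (opposite Celf3), Smtn, Ctcfl (opposite Ctcflos), Tmem252, Hdnr, Tdrkh (opposite Oaz3), Myh11, Hoxb6 and the muscle filament gene Des. All 10 also fell in Erbb2-deficient tumors (edgeR adjusted p at most 0.000499). The Tmem252 row, with the muscle gene Pgm5 as its neighbour, averaged 1694 and 12.6 CPM in controls, and 953 and 14.7 CPM in Erbb2-deficient mice. Against a floor of 3 counts over the group, the muscarinic receptor Chrm2, at 0 in every control tumor, was at least 65.1-fold lower than in adjacent tissue, Riiad1 at least 37.3-fold and Ctcfl at least 26.5-fold lower. Hdnr was at 0 in every tumor of both genotypes and averaged 10.9 CPM in control adjacent tissue.

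In all, 764 rows rose and 776 fell of 7119 in control tumors (edgeR, adjusted p under 0.05). The count of called rows was 2544 without control tumors 2 and 3, and 593 when only the control groups were fitted.

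The same comparison in Erbb2-deficient mice asked which genes mark tumors when the epithelium lacks Erbb2. Most tested Wnt target rows and 3 of 7 matrix gene rows rose in tumors, and 11 of 14 smooth muscle, 5 of 6 colonocyte, 6 of 10 goblet cell and 7 of 12 mitochondrially encoded rows fell. Wnt targets rose in 9 of 10 tested members (9 adjusted over the list alone). Notum averaged 1.12 CPM (0.644 without Erbb2-deficient adjacent 4) in adjacent tissue and 400 CPM in tumors, a log2 fold change of 8.34 ± 1.06 SE (edgeR adjusted p = 1.95e-05), and Nkd1 1.54 and 67.8 CPM. Dkk2 averaged 0.151 CPM in adjacent tissue, from 1 count in Erbb2-deficient adjacent 4, and 24.0 CPM in tumors. The transcription factor Prox1 was at 0 in every adjacent library and at least 70.9-fold higher in tumors, against a floor of 3 counts over the group. Smooth muscle markers fell in 11 of 14 (11 adjusted over the list alone, where 1 rose), with log2 fold changes of -5.69 ± 0.42 SE for Smtn, -5.00 ± 0.42 for Myh11, -5.36 ± 0.60 for Cnn1 and -5.86 ± 0.69 for Des. Camera gave adjusted p = 4.39e-08 for Wnt targets and 1.80e-13 for smooth muscle markers (adjusted p = 0.105 and 0.0137 with an estimated correlation).

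Absorptive colonocyte markers fell in Erbb2-deficient tumors in 5 of 6 members (5 adjusted over the list alone), among them Car4 (30.2 CPM in adjacent tissue and 1.03 CPM in tumors, 0.541 without Erbb2-deficient tumor 4), Slc26a3, Muc3 and Cdhr5. Goblet cell markers fell in 6 of 10 (6 adjusted over the list alone, where 1 rose), among them Clca1 (79.1 and 8.40 CPM), Fcgbp, Zg16 and Bcas1. Fibroblast and matrix genes rose in 3 of 7 (6 adjusted over the list alone): the collagen Col1a1 (3.89 and 31.0 CPM), Sparc and Fn1, while Col3a1 did not pass over all genes (edgeR adjusted p = 0.0722). Mitochondrially encoded rows fell in 7 of 12 (7 adjusted over the list alone), among them CYTB (212 and 67.6 CPM), ND6, ND2 and ND1. The strand limit given for ND6 in controls holds here too. Camera gave adjusted p = 0.00100 for the colonocyte, 0.0153 for the goblet cell, 0.0302 for the fibroblast and 0.0107 for the mitochondrial list. These were adjusted p = 0.506, 0.698, 0.698 and 0.698 with an estimated correlation. The fibroblast list was not called without Erbb2-deficient tumor 2 (0.0648) or Erbb2-deficient adjacent 5 (0.0813), nor with only members without an opposite-strand exon (0.0805), with a range over its alternatives of 0.0148 to 0.698.

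**Figure D4:**
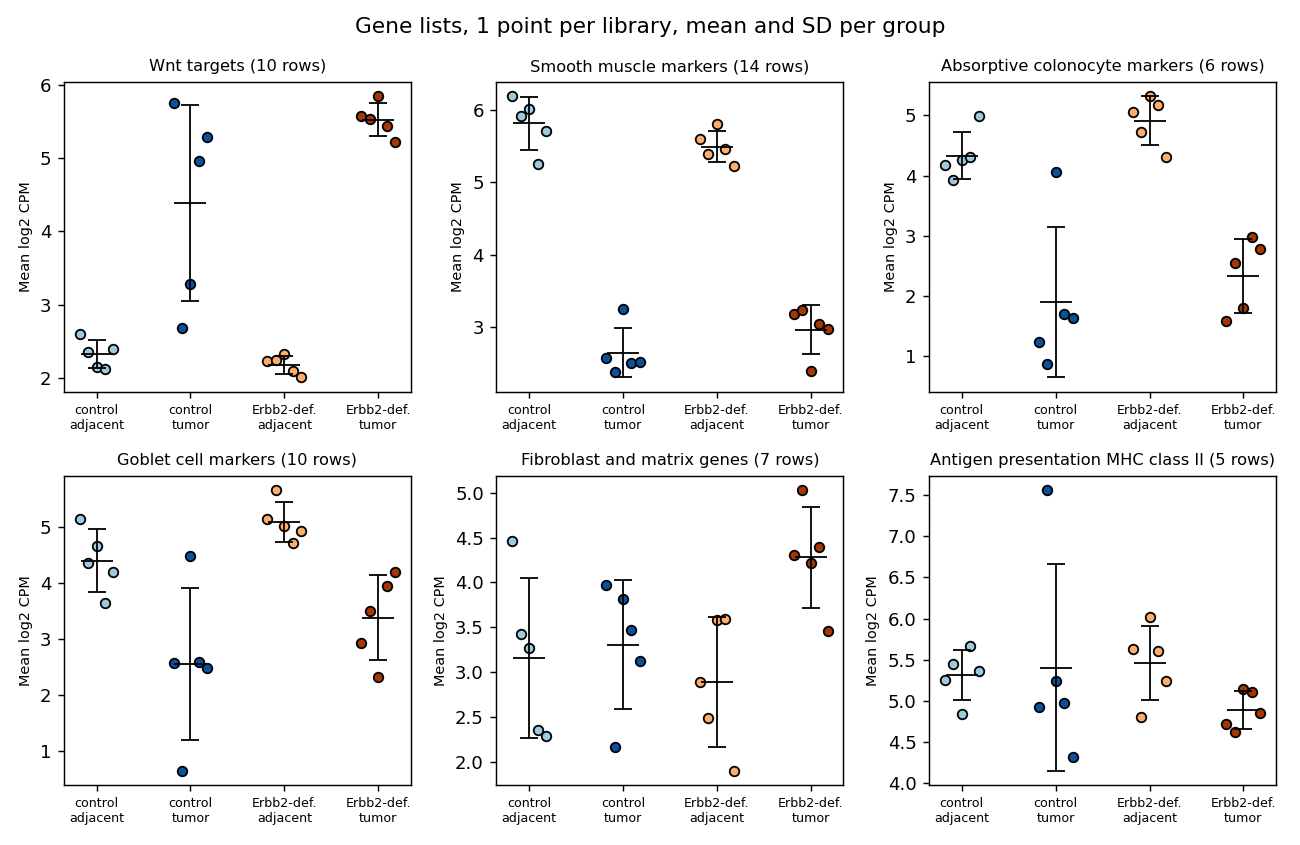
Mean log2 CPM of 6 gene lists, 1 point per library, with mean and SD of the 5 libraries of each group. Smooth muscle means were at least 5.22 in every adjacent library and at most 3.25 in every tumor, and Wnt target means of control tumors 2 and 3 were 2.68 and 3.28.

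The 10 largest rises by the rule in Erbb2-deficient tumors were AV064505, Notum, Prox1, Gata5, LOC118567739, Gata5os, Lyz1, Ush1g (neighbour Otop2), Pilrb1 and Cfi. AV064505 lies opposite Mmp7, a matrix metalloprotease. It averaged 3.37 CPM in adjacent tissue and 5501 CPM in tumors, a log2 fold change of 10.59 ± 1.26 SE (edgeR adjusted p = 1.31e-05), and 7.54 (4.84 without control adjacent 3) and 4525 CPM in control mice, with 7.26 CPM in control tumor 2. Gata5os and Gata5 lie opposite each other, and averaged 0.741 and 166 CPM and 0 and 23.8 CPM. Against the floor of 3 counts over the group, Gata5 was at least 55.5-fold, LOC118567739 at least 51.0-fold, Ush1g at least 29.8-fold, Pilrb1 at least 26.0-fold and Cfi at least 25.0-fold higher. The 10 largest falls were Hoxb7, Chrm2, Mptx1, Tmem252, Des, Smtn, Ermard (opposite Tcte3), Cnn1, Atp12a and Itga7 (opposite Mettl7b). Hoxb7 was at 0 in every tumor and at least 30.5-fold lower. Mptx1, a pentraxin, averaged 19.9 and 0.144 CPM, and the proton pump Atp12a 15.1 and 0.298 CPM.

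In all, 929 rows rose and 1030 fell of 7119 in Erbb2-deficient tumors (edgeR, adjusted p under 0.05), and 2939 were called without control tumors 2 and 3, which enter the shared estimate of the spread. Across the genotypes 576 rows rose in both and 638 fell in both, where independent sets of these sizes would share 99.7 and 112, and 0 went in opposite directions. The log2 fold changes had a Pearson r of 0.84 across 7119 genes, which are not independent replicates.

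The comparison of Erbb2-deficient with control tumors asked whether loss of Erbb2 goes with other expression in tumors. No gene passed in edgeR, which called 0 rows. At an unadjusted p under 0.05 it had 817 of 7119 rows, and 527 of 7516 without control tumor 2. DESeq2 with all libraries called 26 rows, 5 higher and 21 lower in Erbb2-deficient tumors. The rows of smallest p that were higher in Erbb2-deficient tumors were the dynein heavy chain Dync1h1 (log2 fold change 1.28 ± 0.29 SE), Rin2, Il1bos (3.91 CPM in control and 16.6 CPM in Erbb2-deficient tumors, opposite the cytokine Il1b), B9d1 and the matrix protein Mgp. Those that were lower were Tmem140 (-0.87 ± 0.20 SE, opposite Cyren), LOC118568019, LOC118568759, Prr33 (neighbours Lsp1 and Tnnt3) and Palm3 (opposite the interleukin 27 receptor Il27ra). All 10 had edgeR adjusted p = 0.180. Among them DESeq2 called Dync1h1, Rin2, Il1bos, B9d1, Tmem140 and LOC118568759. Of the 10, the 5 that were lower had their highest control tumor level in control tumor 2, such as 1325 CPM for Prr33 and 1521 CPM for Palm3.

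Fibroblast and matrix genes and Wnt targets were ranked higher in Erbb2-deficient tumors by camera (adjusted p = 0.00754 and 0.0144), and 0 of their members passed over all genes or adjusted over the list alone. Both had adjusted p = 0.657 with an estimated correlation. The fibroblast members of smallest p were Col6a1 (2.91 CPM in control, 1.80 without control tumor 3, and 7.72 CPM in Erbb2-deficient tumors), Col3a1, Fn1 and Col5a1. The Wnt members were Dkk2 (11.9 and 24.0 CPM), Axin2, Nkd1 and Wif1. The lists called numbered 2 here, 0 without Erbb2-deficient tumor 2, 8 without Erbb2-deficient tumor 3, 4 without control tumor 3 and 5 without control tumor 4. Absorptive colonocyte and goblet cell markers were ranked higher in Erbb2-deficient tumors without control tumor 3 (camera adjusted p = 0.00436 and 3.28e-05) and without control tumors 2 and 3 together (0.00440 and 0.00366), and not called with all libraries. Wnt targets were not called without control tumor 3 (camera adjusted p = 0.0570), nor without control tumors 2 and 3 together (0.437), whose Wnt list means were 2.68 and 3.28 on the log2 scale against 4.96 to 5.76 in the other control tumors. Without Erbb2-deficient tumor 2 the adjusted p was 0.0514 for Wnt targets and 0.0554 for fibroblast genes, and with only members without an opposite-strand exon it was 0.0656 and 0.0561. The range over alternatives was 5.73e-05 to 0.657 for Wnt targets and 0.000291 to 0.657 for fibroblast genes.

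The comparison of Erbb2-deficient with control adjacent tissue asked the same outside tumors. No gene passed: edgeR called 0 rows, with 418 rows at an unadjusted p under 0.05. DESeq2 called 5, all lower in Erbb2-deficient mice: Cdc27, Epb41, Lrrc47, Snrnp35 and Gm30368, the last chosen after its values were seen. The rows of smallest p that were higher were Otud4 (log2 fold change 2.77 ± 0.63 SE), the splicing factor Srsf5, the translation factor Eif4g2, the histone demethylase Kdm4a and the splicing factor Sf3b1, at edgeR adjusted p = 0.376 to 0.468. Those that were lower were the cell cycle gene Cdc27 (-1.90 ± 0.39 SE, edgeR adjusted p = 0.286), Lrrc47 (opposite Smim1), the membrane skeleton gene Epb41, LOC118567690 and Snrnp35. Without control tumor 2, which enters only the shared estimate of the spread, edgeR called 2 rows, Prr33 and Gm30368, and without control adjacent 5 it called 1, Gm30368.

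Camera ranked 4 lists higher and 1 lower in Erbb2-deficient adjacent tissue, with 0 members past the threshold over all genes. Oxidative phosphorylation genes (adjusted p = 0.0164) had the smallest p for Sdha (2.57 CPM in control, 1.30 without control adjacent 3, and 9.78 CPM in Erbb2-deficient tissue), Cox5b, Atp5b and Atp5a1. The fetal-like epithelial list (adjusted p = 0.0167) had it for Krt23 (0.350 and 3.06 CPM), Clu, S100a6 and Krt7, and goblet cell markers (adjusted p = 0.0167) for Spink4 (11.5 and 27.3 CPM), Zg16, Agr2 and Bcas1. Mitochondrially encoded rows (adjusted p = 0.0167) were led by CYTB (107 and 212 CPM), COX2, COX1 and ND1, and 2 of 12 passed adjusted over the list alone. Within each genotype, adjacent libraries differed in the share of counts on their 10 highest rows. That share was 16.5% to 30.7% in Erbb2-deficient and 20.9% to 33.0% in control tissue, and was not adjusted for. Smooth muscle markers were lower (adjusted p = 0.0164), led by Smtn (884 and 439 CPM), Lmod1, Actg2 and Acta2. With an estimated correlation none of these lists stayed called: camera adjusted p was 0.647 for oxidative phosphorylation and the fetal-like list, and 0.862 for the other 3. The lists called numbered 5 here, 0 without control adjacent 2, 1 without control adjacent 4 or Erbb2-deficient adjacent 1, and 3 without Erbb2-deficient adjacent 2 or control adjacent 1, 3 or 5. Smooth muscle markers were the list called without control adjacent 4 or Erbb2-deficient adjacent 1.

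The interaction asked whether the difference between tumor and adjacent tissue depends on genotype. A higher tumor difference means a higher log2 fold change of tumor against adjacent tissue, so a smaller fall also counts as higher. No gene passed: edgeR called 0 rows, with 290 rows at an unadjusted p under 0.05, and DESeq2 called 0. The rows of smallest p toward a higher tumor difference in Erbb2-deficient mice were Ttll11 (2.16 ± 0.58 SE on the log2 scale), the caveolar gene Cavin1, Cdc27, Zfp651 and Tigd5 (neighbour Eef1d). Toward a lower one they were Med22 (-1.90 ± 0.52 SE, neighbour Rpl7a), BC051537 (opposite H2-Oa), Ms4a6c, Tctn1 (opposite the proton channel Hvcn1) and Cirbp. All 10 had edgeR adjusted p = 1.0. BC051537, Ms4a6c and Tctn1 had 1873, 2993 and 8667 CPM in control tumor 2.

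Fibroblast and matrix genes, smooth muscle markers and Wnt targets were ranked by camera toward a higher tumor difference in Erbb2-deficient mice (adjusted p = 7.86e-05, 0.00205 and 0.00275), each with adjusted p = 0.599 with an estimated correlation. The members of smallest p were Col1a1 (2.60 ± 1.11 SE on the log2 scale, with a mean of 11.0 CPM in control adjacent tissue that was 4.91 without control adjacent 1), Col5a1, Col3a1 and Col6a1, then Smtn (1.68 ± 0.54 SE), Csrp1, Tpm2 and Acta2, and Nkd1 (1.80 ± 1.12 SE, with a mean of 35.4 CPM in control tumors that was 21.4 without control tumor 1), Dkk2, Prox1 and Tcf7. Of these members 0 passed over all genes or adjusted over the list alone. Most smooth muscle rows fell in tumors of both genotypes, so for that list the higher difference was a smaller fall in Erbb2-deficient mice. The lists called numbered 3 here, 7 without control tumor 3, 6 without control tumor 4, and 5 without control tumor 1 or 5, control adjacent 4, Erbb2-deficient tumor 3, or Erbb2-deficient adjacent 2 or 5. The added lists were others, such as MAPK output. Control tumor 2 stayed in each of these fits, and its mean of the MAPK list was 2.53 on the log2 scale. In the other control tumors that mean was 4.37 to 5.14. Wnt targets were not called without control tumors 2 and 3 together (camera adjusted p = 0.364), nor with only members without an opposite-strand exon (0.0524), with a range over alternatives of 0.000501 to 0.777.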

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

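The tests of the strand, of control tumor 2, of smooth muscle and of the lists in other splits were chosen after the results they measure were seen. The splits of gene counts were planned. The planned tests of smooth muscle, sex and lymphoid share as sources of genotype calls are void, since edgeR called 0 genes in both genotype comparisons (817 and 418 rows at an unadjusted p under 0.05, and 26 and 5 called by DESeq2).

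In single libraries, 21 of 212 groups of values of named rows held a library far from the other 4, where chance gives about 10.6, and so did 2 of 48 groups of list means and other library values, where chance gives about 2.4. Of the 21, 10 were in control tumor 2: 391 CPM for Tmem140, 465 for LOC118568019, 148 for LOC118568759, 1325 for Prr33, 1521 for Palm3, 7.26 for Des, 28.1 for Med22, 1873 for BC051537, 2993 for Ms4a6c and 8667 for Tctn1. Control tumor 3 stood out by 35.0 CPM for Itga7 and by the list means of smooth muscle (3.25) and absorptive colonocyte markers (4.06). The others were Otud4 (9.82 CPM) and Des (3.02) in Erbb2-deficient tumor 1, Tdrkh in Erbb2-deficient tumor 5 (9.37) and Erbb2-deficient adjacent 1 (128), Hoxb7 in Erbb2-deficient adjacent 1 (22.1) and control adjacent 1 (37.5), Eif4g2 (42.9) and Tctn1 (929) in Erbb2-deficient adjacent 3, and Ctcfl (22.9) and Mptx1 (0) in control adjacent 3.

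The tumor difference of 3 lists differed between genotypes by camera: Wnt targets (adjusted p = 0.00275), fibroblast and matrix genes (7.86e-05) and smooth muscle markers (0.00205). All 3 had adjusted p = 0.599 with an estimated correlation, and Wnt targets had 0.364 without control tumors 2 and 3.

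Few reads lay on genes, 2.51% to 3.45% of the reads in a file. Genomic DNA would put reads on the Tsix row in every library, and 11 libraries had at most 1 count there. Chromosome names that differ between annotation and alignment would leave chromosomes without counts, and 0 of chromosomes 1 to 19 and X lacked them in any library, while a shift of coordinates would spread reads by exon length, and rows with an exon of another gene opposite, 29.3% of exon bases, held at least 75.1% of the matched counts in each library. Stranded reads counted on the opposite strand may be the cause, since the ND6 row exceeded the other mitochondrial protein gene rows together in 20 libraries. No biological explanation was tested.

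Control tumor 2 stood apart from the other tumors. Low depth is argued against by its total on genes, 94.7% of the median of the other 19 libraries, and a swap with an adjacent library by its smooth muscle mean, at -2.84 against the lowest adjacent library on the log2 scale. Lymphoid tissue in place of epithelium is a candidate explanation: 12 of 14 lymphoid rows were highest of all libraries in it, and 14 of 16 epithelial rows were at 0. Independent rows would give 0.7, but several of these rows lie opposite each other and the library was chosen because it stood apart. The exceptions were Itgae (28.1 CPM) and the B cell marker Ms4a1, at 3.63 CPM against up to 20.6 CPM in Erbb2-deficient adjacent 3. Control tumor 2 had 501, 482 and 141 CPM in the Bcl9l (opposite Cxcr5), Dexi (opposite Ciita) and Cd74 rows. Whether the sample held a lymphoid follicle of the colon or came from elsewhere stays open.

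Smooth muscle rows were lower in tumors. More of all non-epithelial tissue in adjacent samples would lower fibroblast genes in tumors too, and their lower median log2 fold change of both genotypes was 0.29. This does not exclude it, since the 7 tested rows had few counts and a rise of matrix genes within tumors could hide such a fall. Muscle layer taken along in uneven amounts was predicted to make smooth muscle means vary more than colonocyte means among adjacent libraries, and to overlap with tumors. Neither was seen, with SDs of 0.328 and 0.485 and a gap of 1.97 between the lowest adjacent and the highest tumor library on the log2 scale. Muscle layer taken along evenly cannot be told apart from muscle that belongs to that tissue, since the gap would come with either. A biological difference of the tissues stays open and untested.

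Other splits of the libraries, 100 per comparison with the real one, were tested with edgeR for genes and camera for lists. Chance can be excluded for gene counts of tumor against adjacent tissue in controls (1540, highest other 761, 1 split as large) and in Erbb2-deficient mice (1959, highest other 1, 1 split). For tumor genotype, adjacent genotype and the interaction the real count was 0, so all 100 splits gave as many by construction and the test says nothing (highest other 2, 477 and 1). The split with 477 genes set Erbb2-deficient adjacent 1, 2 and 5 and control adjacent 1 and 5 against the rest, which points to a structure of the adjacent libraries. The named libraries had 78.6% to 80.2% of reads on no feature, and the other adjacent libraries 82.0% to 84.1%. Their 10 highest rows held 24.5% to 33.0% of counts on genes, against 16.5% to 22.0%. The cause of this difference was not tested. For list counts chance cannot be excluded for tumor genotype (2, highest other 11, 64 splits), adjacent genotype (5, highest other 8, 5 splits) and the interaction (3, highest other 9, 34 splits). For tumor against adjacent tissue the list counts (5, highest other 9, 25 splits in controls, and 6, highest other 8, 11 splits in Erbb2-deficient mice) decide nothing, since other splits keep part of the tissue difference: those with 4 tumors on 1 side called a median of 4 lists in controls and 5 in Erbb2-deficient mice, and those with 3 tumors 3 and 1.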

How the results depend on the processing

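The fits without control tumors 2 and 3, without control tumor 2 where it enters only the spread, on genes or list members without an opposite-strand exon and on partner lists were chosen after seeing the data. Except where said, the cause of a change was not tested.

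In the order tumor genotype, adjacent genotype, control and Erbb2-deficient tumor against adjacent tissue, and interaction, edgeR called 0, 0, 1540, 1959 and 0 genes, and 0, 0, 1428, 1989 and 0 with a replicate block (3, 5, 4, 7 and 3 lists, with goblet cell markers gained for tumor genotype, endothelial markers gained in Erbb2-deficient mice and the mitochondrial list lost in controls). For both genotype comparisons the block was the replicate number alone. It joined different mice of the 2 genotypes that only share a number, so the goblet cell gain carries no weight. For the other comparisons the block was genotype and number together. The labels give only shared numbers: libraries of the same genotype and number, as deviations from group means, had r of -0.115 to 0.370, over 0.1 in 6 of 10 pairs, and 4 of 10 tumor libraries correlated best with their own number. In 0 of 10 pairs was the Tsix row above 50 CPM in only 1 library, and in control pair 1 it was at an intermediate 109 and 97.7 CPM. DESeq2 called 26 genes for tumor and 5 for adjacent genotype. Without a filter adjacent genotype had 1 (Gm30368), and without control tumors 2 and 3 it had 1 (Prr33), with 2544 and 2939 in the tumor comparisons. A smooth muscle covariate, which separates the tissues, left 0 in both. A test against a 1.5-fold change called 772 and 1139, and a fit of the control groups alone 593. Rows without a known opposite-strand exon, which are fewer and include the unmatched rows, gave 851 and 1087. Leaving out 1 library gave 0 to 0, 0 to 2, 1188 to 2127, 1573 to 2719 and 0 to 0 genes. Adjacent genotype had 2 (Prr33 and Gm30368) without control tumor 2 and 1 (Gm30368) without control adjacent 5.

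The Erbb2 log2 fold change in tumors, 0.02, was -0.16 without control tumors 2 and 3. Leaving out 1 library gave -0.32 to 0.28, negative without Erbb2-deficient tumor 2 (-0.11) or 4 (-0.32) or control tumor 2 (-0.23) or 5 (-0.06). In adjacent tissue it was 0.33 to 0.80. Erbb2 was not tested in the fit of the tumor groups alone.

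In the same order camera called 2, 5, 5, 6 and 3 lists. With an estimated correlation it called 0, 0, 1, 1 and 0, with fry 0, 0, 9, 11 and 0, and with partner lists 0, 2, 2, 1 and 1. Among lists called for tumor against adjacent tissue, only smooth muscle markers had at least 3 tested partner rows. The others were not tested on partner rows. Smooth muscle markers stayed called in every camera and fry alternative, at adjusted p of at most 0.00198 in controls and 0.0137 in Erbb2-deficient mice. With members without an opposite-strand exon tumor genotype had 0. Leaving out 1 library gave 0 to 8, 0 to 5, 4 to 5, 5 to 7 and 3 to 7.

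Of 4742 alternatives for 190 results (rows picked by the rule, tested ERBB members other than Erbb2, leading members of called lists, and Mien1), 4543 kept direction and side of the threshold, 136 lost their call (83 with the smooth muscle covariate), 31 gained one (13 with DESeq2) and 32 reversed. Of these 28 were with that covariate. In controls tumor against adjacent tissue it gave log2 fold changes of -0.10 for Ush1g, 0.0642 for Cnn1, 1.82 for Itga7, 2.23 for Egfr, -0.0842 for Nrg4, -0.66 for Lrig1, -1.78 for Lef1, 3.02 for Cdhr5, 0.45 for Slc26a3, 4.70 for Muc3, 1.19 for Clca1, 2.69 for Fcgbp, 3.78 for Tff3, 3.01 for Bcas1, 0.62 for CYTB and 0.39 for ND1, and in Erbb2-deficient mice 2.14 for Egfr, -0.16 for Nrg4, 2.98 for Muc3, 2.44 for Cdhr5, 0.70 for Clca1, 1.87 for Fcgbp, 4.12 for Zg16 and 1.67 for Bcas1, none called. For genotype it gave 0.0186 for Nrg4 in tumors and 0.15 for Acta2 in adjacent tissue, and for the interaction -0.10 for Egfr and -0.32 for Acta2. Leaving out 1 library gave -0.12 to 0.00072 for Nrg4 by tumor genotype (positive without control tumor 4) and -0.18 to 0.24 for Egfr by adjacent genotype (negative without control adjacent 2 or 4 or Erbb2-deficient adjacent 5). In data simulated from mean levels and dispersions over all 20 libraries, 13 of 100 genes changed 2-fold and 59 of 100 changed 4-fold were called by tumor genotype. The wider spread among control tumors was not simulated, and depth and spread were not varied apart. Of the ERBB list, 12 members had too few counts to be tested, which does not show low expression, since housekeeping rows also had few counts.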

Other observations

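Proliferation and antimicrobial genes, with single members past the threshold between tumors and adjacent tissue, were not called as lists by camera with all libraries and their own rows. Of 7 tested proliferation genes 4 rose in control tumors (Mki67, Ccna2, Aurka and Top2a; camera adjusted p = 0.141) and 3 in Erbb2-deficient tumors (Ccna2, Aurka and Pcna; 0.138). The proliferation list was called higher in tumors by fry (adjusted p = 0.00799 in controls and 0.00396 in Erbb2-deficient mice), and in controls by camera on partner rows (0.0390). Of 4 tested genes of epithelial antimicrobial defence Saa1 and Pigr fell and Lyz1 rose in both genotypes, with Saa1 at 84.9 CPM in adjacent tissue and 10.6 CPM in tumors of controls and 105 and 16.7 CPM in Erbb2-deficient mice. These members were chosen after their values were seen.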
